A study of Homo sapiens with 24 samples.

How the data were processed

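RNA of the human ovarian cancer cell lines A2780 and ES2 was sequenced in 24 libraries, which the titles place in 8 groups of 3: each line with a control siRNA, with an siRNA against VRK1, with the solvent DMSO and with luteolin. Total RNA was extracted with a column kit, and an outside company made and sequenced the libraries, per the labels' protocols. The submitters' processing notes name FastQC, kallisto and the human build hg19, without versions and without saying which transcript set was counted. The deposited table holds 1 TPM value per transcript and library, with a gene symbol per transcript. It has 193845 lines for 191887 transcripts, and the 1958 repeated lines carried identical values, so each transcript was used once. The TPM of the distinct transcripts added to 1000000 in each library, so the sequencing depth cannot be read from the table and is unknown. No interval for counting error could therefore be given, and precision rests on the spread between libraries alone.

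The labels needed a reading in 3 places. The cell line label counts up within each line and the treatment label of the later siVRK1 libraries of a line reads siVRK2 and siVRK3, while the titles name 1 line and siVRK1 throughout. The titles were used, and VRK1, VRK2 and VRK3 were compared in every library. A pair of ES2 siVRK1 columns share 1 name, so these 2 libraries are called a and b here, beside the numbered library 3. No per-sample column was left out.

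Gene TPM was the sum over the transcripts of a symbol, which gave 28907 symbols. Left out were 19 transcripts with more than 1 symbol and 9542 without a symbol, which held 0.514% to 1.03% of the TPM of a library. Each comparison used limma 3.58.1 in R 4.3.3 (limma-trend on the log2 of TPM + 1, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p). Genes with a TPM of at least 1 in at least 3 libraries of the fit were tested. Comparisons within a line, including the difference between its treatments, used the 12 libraries of that line. The differences between the lines used all 24 libraries. Fold changes are on the log2 scale of TPM + 1, which understates the change of genes near or below 1 TPM, and values after ± are standard errors of the fit unless SD is named. Where rescaling the libraries moved the median change of all genes by more than 0.1, gene values are given relative to that median.

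The genes named in the text follow a rule: VRK1, VRK2 and VRK3, then for each treatment the 10 largest rises and 10 largest falls among genes past the threshold, without overlap between treated and control libraries, with a mean of at least 5 TPM in the higher group and with an established symbol. The rule adds up to 2 rises and 2 falls from each gene list, 5 genes per direction for each difference between effects, and 5 per direction for each overlap of calls. The text names some of these. Genes that share sequence with near-identical copies, such as pseudogenes, replication-dependent histone genes and T-cell receptor segments, are uncertain because kallisto divides reads between such copies, and overlapping genes are uncertain because no strand setting is given in the sources used here.

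For groups of genes, 27 lists with 613 genes were written, and all 613 were found in the table. Of these, 22 lists of pathways and gene classes were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, and fry, which asks whether a list moves on balance one way. Members were also counted with p-values adjusted over the list alone. The other 5 lists held markers of leukocytes, endothelium, fibroblasts, erythroid cells and melanocytes and were read as TPM. The design, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

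The alternatives were pseudocounts of 0.1 and 5, no filter and a stricter filter of 5 TPM, median-of-ratios scaling, quantile normalization, other sets of libraries in the fit, a robust prior variance, the replicate number as a block, and leaving out each library in turn. Another 3 were added after the data had been seen: the block with the unnumbered libraries in the other order, removal of the 13 mitochondrial mRNAs, and removal of genes with 1 sequence word in their 3′ UTR. That word came from a search of 7-base words in the 3′ UTRs of GENCODE release 29, whose transcript IDs matched 168792 of the transcripts, over genes of at least 5 TPM. The steps were tested on simulated data with 200 changed genes, all drawn from genes above about 5 TPM, so the recovery of lower genes was not measured. Of 100 genes changed 2-fold, 98% were recovered for A2780 siVRK1 among 13012 genes, 97% for ES2 siVRK1 among 12507 and 96% for the difference between the lines among 14328. Of 100 genes changed 1.5-fold, 84%, 88% and 61% were recovered in the same order. Other tools were Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.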

Results

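Transcript levels were measured by RNA sequencing in 2 human ovarian cancer cell lines, A2780 and ES2. Each line was given a control siRNA (siCtrl), an siRNA against VRK1 (siVRK1), the solvent DMSO or luteolin, a flavone from plants, with 3 libraries in each of the 8 groups. VRK1 is a nuclear serine/threonine kinase. The dose of luteolin and the times of treatment are not given in the sources used here. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which can be technical. The values were TPM, which keep no record of sequencing depth, and between 11792 and 12862 genes reached 1 TPM in a library. Log2 levels of libraries from 1 group correlated across genes at 0.990 to 0.994, against 0.951 to 0.981 between groups of A2780 and 0.943 to 0.975 between groups of ES2, where genes are not independent replicates. The first principal component held 83.4% of the variance and separated the lines. Mitochondrial mRNAs took 4.03% to 12.1% of the TPM of a library.

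VRK1 was lower in each siVRK1 library than in any control library of its line. The gene lies on the plus strand of chromosome 14 from 96797304 to 96931722 (GRCh38, GENCODE release 29), and the table lists 7 of its transcripts. In A2780 it fell from 54.4 ± 0.788 TPM (SD, n = 3) with siCtrl to 9.57 ± 1.68 TPM with siVRK1, a log2 fold change of −2.40 ± 0.11 (limma adjusted p = 1.75e-08). In ES2 it fell from 64.6 ± 2.17 TPM to 3.73 ± 0.703 TPM, a log2 fold change of −3.80 ± 0.11 (adjusted p = 6.94e-11). Luteolin lowered VRK1 in A2780, from 54.2 ± 5.04 TPM with DMSO to 39.9 ± 3.92 TPM (log2 fold change −0.43 ± 0.11, adjusted p = 0.00357, or −0.65 relative to the median of all genes). In ES2 the levels were 60.3 ± 3.20 TPM with DMSO and 61.5 ± 7.18 TPM with luteolin, and no difference was called (0.02 ± 0.11, adjusted p = 0.881). The sign of that last value turned when ES2 luteolin library 3 was left out (−0.0518) and when ES2 DMSO library 1 was left out (−0.01). The related kinase VRK2 fell less with siVRK1, by 0.28 on the log2 scale in A2780 (adjusted p = 0.0194) and by 0.34 in ES2 (adjusted p = 0.000417). VRK3 was not called in A2780 (−0.14 ± 0.08, adjusted p = 0.169) and fell by 0.24 in ES2 (adjusted p = 0.0109). The libraries whose treatment label reads siVRK2 or siVRK3 had VRK1 as low as the others of their group, between 7.98 and 11.3 TPM over the A2780 group and between 2.92 and 4.20 TPM over the ES2 group.

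**Figure D1:**
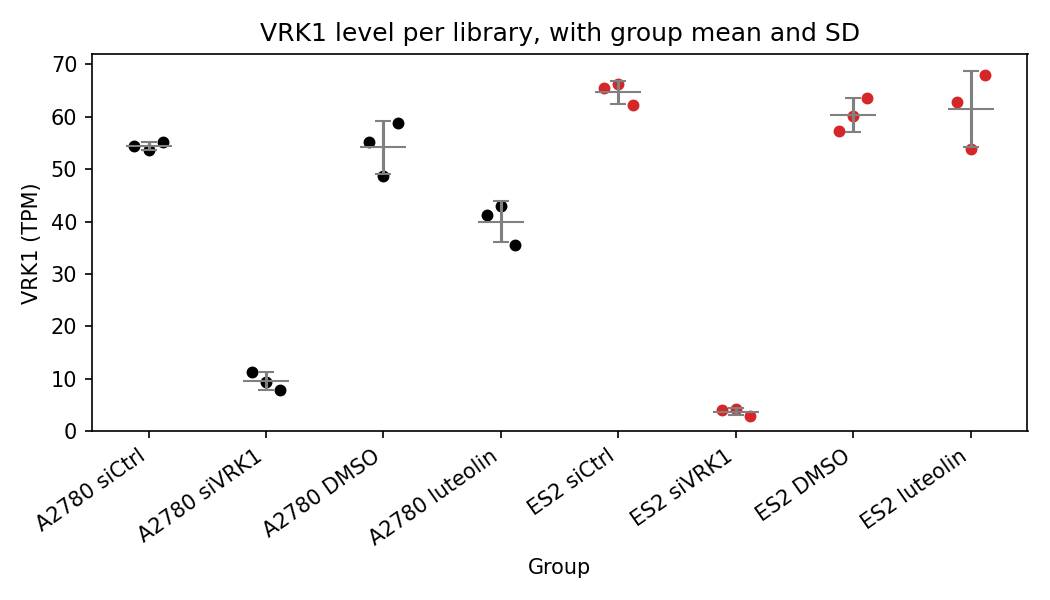
VRK1 in TPM (vertical axis) in each of the 24 libraries, by cell line and treatment; points are libraries, horizontal lines group means and error bars SD (n = 3). With siVRK1 the mean was 9.57 TPM in A2780 and 3.73 TPM in ES2, against 54.4 and 64.6 TPM with siCtrl.

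With siVRK1 in A2780, TAGLN, ACTA2 and CCN2 were higher and most listed cell-cycle transcripts were lower. TAGLN, an actin-binding protein of smooth muscle, rose from 183 to 859 TPM (log2 fold change 2.23 ± 0.05), and the smooth muscle actin ACTA2 rose from 32.9 to 160 TPM (2.25 ± 0.06). CCN2, a secreted growth factor of connective tissue, rose from 19.7 to 102 TPM (2.31 ± 0.08). The enteric actin ACTG2 went from 0.652 to 14.7 TPM and the atrial myosin light chain MYL7 from 1.41 to 20.3 TPM, low control levels at which a fold rests on the pseudocount. The largest falls after VRK1 were the metallothionein MT2A (−2.35 ± 0.18, from 90.6 to 17.5 TPM), the endocytic receptor CUBN (−2.21 ± 0.20), the proteoglycan BCAN (−2.17 ± 0.11) and ERAP1 (−2.12 ± 0.11), an aminopeptidase that trims antigenic peptides. The hydroxylase ASPH (−1.68 ± 0.09), the Golgi GTPase ARL1 (−1.68 ± 0.12) and the kinetochore protein SKA2 (−1.67 ± 0.09, from 139 to 42.9 TPM) followed. Of the 9 largest falls whose 3′ UTR could be searched, 6 (MT2A, CUBN, ERAP1, S100A2, ASPH and SKA2) held the 7-base word GATAATA there, and 0 of the 9 searched largest rises did; the word came from a search over all such words made after the data had been seen. In all, 1799 genes were higher and 3519 lower of 13012 tested, 104 and 151 of them by at least 2-fold. With median-of-ratios scaling the split was 2687 higher and 2658 lower, so the share of higher calls moved from 33.8% to 50.3% while the median change of all genes moved from −0.08 to 0.00.

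Cell division and DNA replication lists fell in A2780 with siVRK1. Of 36 tested G2/M and mitosis genes, 34 were lower and 1 higher, the same numbers when adjusted over the list alone (median −0.56, camera adjusted p = 1.5e-10, and adjusted p = 0.438 with an estimated correlation). They included NUSAP1, which bundles spindle microtubules (−1.07 ± 0.11), and cyclin A2, CCNA2 (−1.05 ± 0.09). Of 40 G1/S and DNA replication genes, 36 were lower, or 37 adjusted over the list alone, and 0 higher (median −0.46, adjusted p = 1.04e-10, and adjusted p = 0.422 with an estimated correlation), among them cyclin E1, CCNE1 (−1.03 ± 0.06), and the polymerase subunit POLA2 (−0.96 ± 0.13). With median-of-ratios scaling the lower members of these lists numbered 29 and 31. Of 29 homologous recombination and Fanconi genes, 24 were lower, or 25 adjusted over the list alone (median −0.48, adjusted p = 3.69e-06, and adjusted p = 0.422 with an estimated correlation), FANCD2 (−0.96 ± 0.20) and the helicase-nuclease DNA2 (−0.93 ± 0.13) among them, and 22 with that scaling.

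Most heat shock and cholesterol genes also fell there, while part of the matrix genes and of the p53 targets rose. Among 17 heat shock genes 15 were lower, also when adjusted over the list alone (median −0.31, adjusted p = 6.17e-06, and adjusted p = 0.422 with an estimated correlation), and 14 were with median-of-ratios scaling, with the chaperone HSP90AA1 at −0.64 ± 0.06 (747 to 478 TPM). Of 24 genes of cholesterol synthesis and uptake 16 were lower and 1 higher, or 17 and 1 adjusted over the list alone and 15 and 2 with that scaling (median −0.36, adjusted p = 0.000162, and adjusted p = 0.422 with an estimated correlation), with the enzymes SC5D (−1.16 ± 0.11) and HSD17B7 (−1.15 ± 0.13). Of 26 extracellular matrix and mesenchymal genes 13 were higher and 2 lower, the same adjusted over the list alone, and 14 and 2 with that scaling (median 0.30, adjusted p = 5.34e-07, and adjusted p = 0.422 with an estimated correlation). Of 6 tested fibroblast markers, 2 of which are also on the matrix list, 4 were higher and 1 lower (median 0.56). The 2 lower members of the matrix list were the transcription factor SNAI2 (−0.58 ± 0.10) and the intermediate filament VIM (−0.32 ± 0.03). The 31 p53 targets went both ways, with 12 higher and 4 lower under either adjustment and 15 and 4 with that scaling (median 0.08, adjusted p = 0.000162, and adjusted p = 0.422 with an estimated correlation). The cell-cycle inhibitor CDKN1A rose from 173 to 355 TPM (1.03 ± 0.07), and the ubiquitin ligase MDM2 fell (−0.73 ± 0.10). These 7 lists were those past the threshold of camera, and 0 were with an estimated correlation.

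In ES2, ESM1 and IL11 rose with siVRK1, COL6A3 and MT2A fell, and most G1/S genes were higher. CHRDL1, which binds BMP growth factors, rose from 2.32 to 36.1 TPM (3.49 ± 0.09), the cytokine IL11 from 2.68 to 28.6 TPM (3.02 ± 0.29) and the endothelial proteoglycan ESM1 from 55.8 to 411 TPM (2.86 ± 0.06). The matrix protein CCDC80 (2.54 ± 0.12), the adenylate kinase AK5 (2.49 ± 0.11) and the proton-sensing receptor GPR4 (2.29 ± 0.13) followed. The collagen chain COL6A3 fell from 64.6 to 6.06 TPM (−3.22 ± 0.09) and MT2A from 7442 to 818 TPM (−3.19 ± 0.07). CFAP251 (−2.85 ± 0.22), WFDC3 (−2.78 ± 0.29), the myelin protein MBP (−2.65 ± 0.13) and VPS4B, an ATPase of the ESCRT machinery (−2.55 ± 0.11, 45.1 to 6.98 TPM), also fell. GATAATA was present in the 3′ UTR of MT2A, MBP and VPS4B among 10 searched largest falls, and of EMP2 among 8 searched largest rises. The leukocyte marker CD68 went from 36.7 to 75.4 TPM (log2 fold change 1.02 ± 0.08). In all, 3351 genes were higher and 3505 lower of 12507 tested, 343 and 466 of them by at least 2-fold.

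G1/S and DNA replication genes rose in ES2 with siVRK1: 28 of 40 were higher and 3 lower, or 29 and 4 adjusted over the list alone (median 0.51, adjusted p = 6.42e-07, and adjusted p = 0.46 with an estimated correlation). The thymidylate synthase TYMS rose from 147 to 431 TPM (1.55 ± 0.07). G2/M genes went both ways, with 16 higher and 9 lower of 36, or 17 and 9 adjusted over the list alone, and the list did not pass (median 0.05, adjusted p = 0.234). PRC1, which bundles microtubules of the central spindle, was higher (1.68 ± 0.04), as was the kinesin KIF20A (1.38 ± 0.06), while CCNA2 was lower (−1.15 ± 0.05). The p53 targets did not pass either, with 7 higher and 6 lower of 29 under either adjustment (median 0.04, mean −0.03, adjusted p = 0.956), and CDKN1A rose from 4.86 to 14.6 TPM (1.41 ± 0.16) while MDM2 fell (−1.53 ± 0.17).

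Heat shock, aryl hydrocarbon receptor, NRF2, matrix and ER chaperone lists fell in ES2 with siVRK1. Of 17 heat shock genes 16 were lower and 1 higher under either adjustment (median −0.33, adjusted p = 4.64e-06, and adjusted p = 0.074 with an estimated correlation), with HSP90AA1 at −0.85 ± 0.03. All 6 tested targets of the aryl hydrocarbon receptor were lower under either adjustment (median −0.84, adjusted p = 0.000596, and adjusted p = 0.074 with an estimated correlation), with the serpin SERPINB2 falling from 925 to 239 TPM (−1.95 ± 0.04). Among 28 targets of NRF2, the regulator of antioxidant genes, 17 were lower and 5 higher under either adjustment (median −0.28, adjusted p = 0.00913, and adjusted p = 0.074 with an estimated correlation). The reductase AKR1C3 fell (−1.90 ± 0.10) and the heme oxygenase HMOX1 rose (1.90 ± 0.07). Of 29 extracellular matrix and mesenchymal genes 19 were lower and 6 higher under either adjustment (median −0.32, adjusted p = 0.00674, and adjusted p = 0.46 with an estimated correlation), with TGFBI lower (−2.09 ± 0.07) and fibronectin FN1 higher (1.45 ± 0.06). Of 4 tested fibroblast markers 2 were lower and 0 higher (median −0.33). Of 20 ER chaperone and unfolded protein response genes 13 were lower and 3 higher, or 14 and 3 adjusted over the list alone (median −0.29, adjusted p = 0.00741, and adjusted p = 0.487 with an estimated correlation), with HERPUD1 of ER-associated degradation lower (−0.86 ± 0.20). With an estimated correlation 0 of the 6 lists passed.

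Between the lines, siVRK1 moved many genes the same way. Of 11304 genes tested in both, 884 were higher in both lines (412 expected from independent lists) and 1723 lower in both (924 expected). Of the genes called in both, 81.9% moved the same way (50.3% expected), and the fold changes correlated across genes at r = 0.46. Among the shared rises were the actin-binding NEXN (1.44 ± 0.09 in A2780 and 1.88 ± 0.06 in ES2) and the chondroitin polymerizing factor CHPF (1.42 ± 0.05 and 1.54 ± 0.06). MT2A, ERAP1 (−2.12 ± 0.11 and −2.50 ± 0.17), SKA2 (−1.67 ± 0.09 and −2.34 ± 0.12) and the butyrophilin BTN3A2 were among the shared falls, and 3 of the 5 named shared falls held GATAATA. Without genes whose 3′ UTR held that word, 855 were higher in both (410 expected) and 1368 lower in both (733 expected). Of the genes then called in both, 80.5% moved the same way (49.3% expected), with r = 0.40. CCN2 (2.31 ± 0.08 and −1.03 ± 0.12) and its relative CCN1, which held the word as well, rose in A2780 and fell in ES2 (CCN1 at −1.06 ± 0.09). The oxidase NOX4 fell in A2780 (−0.86 ± 0.15) and rose in ES2 (1.52 ± 0.17).

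The difference between the lines in the response to siVRK1 was tested directly, and most G1/S and G2/M genes were more positive in ES2. The effect was more positive in ES2 for 2962 genes and more negative for 1897 of 14328. With median-of-ratios scaling these were 2255 and 2762, so that the share of higher calls moved from 61.0% to 44.9%. For the G1/S list 37 of 40 members were higher in ES2 and 0 lower, or 39 adjusted over the list alone and 37 with median-of-ratios scaling (median 0.92, adjusted p = 2.99e-23, and adjusted p = 0.0668 with an estimated correlation). G2/M genes differed likewise, with 32 of 36 higher, or 33 adjusted over the list alone and 30 with that scaling (median 0.63, adjusted p = 1.11e-13, and adjusted p = 0.207 with an estimated correlation). The homologous recombination and Fanconi list had 24 of 29 higher, or 25 adjusted over the list alone and 20 with that scaling (median 0.56, adjusted p = 9.86e-07, and adjusted p = 0.207 with an estimated correlation). Targets of the aryl hydrocarbon receptor (4 of 7 lower, 5 adjusted over the list alone and with that scaling, median −0.51, adjusted p = 2.82e-05, and adjusted p = 0.0175 with an estimated correlation) and matrix genes (18 of 32 lower and 3 higher under either adjustment, 19 and 2 with that scaling, median −0.48, adjusted p = 6.24e-10, and adjusted p = 0.0237 with an estimated correlation) were more negative in ES2. Of 7 tested fibroblast markers 5 were lower in this difference and 0 higher (median −0.52).

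**Figure D2:**
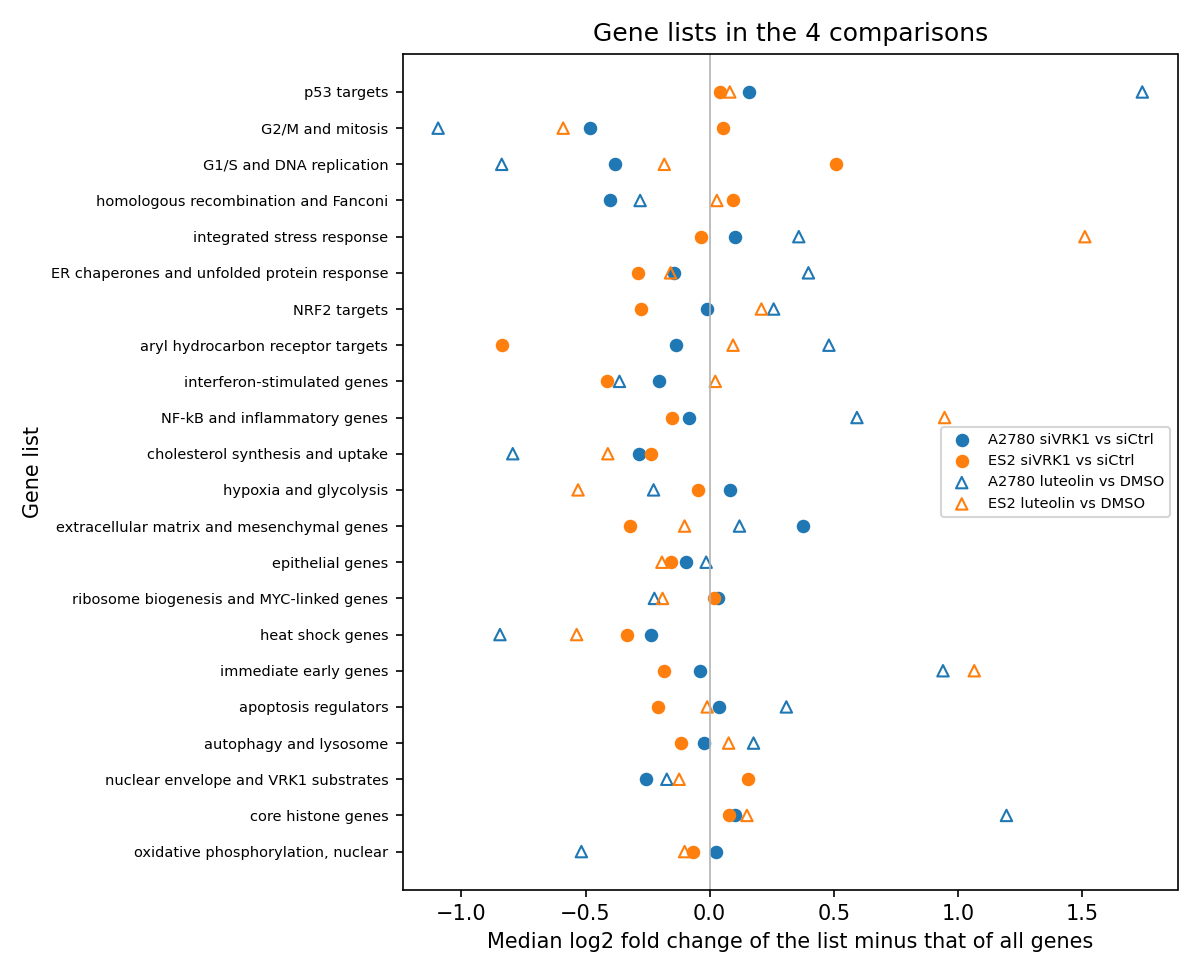
Median log2 fold change of each of 22 gene lists minus the median of all genes tested (horizontal axis), for siVRK1 against siCtrl and luteolin against DMSO in each line; each point is 1 list in 1 comparison of 3 with 3 libraries. The G1/S list was at −0.38 in A2780 and 0.51 in ES2 with siVRK1, and the p53 target list was at 1.74 in A2780 and 0.08 in ES2 with luteolin.

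Luteolin in A2780 raised 30 of 31 p53 targets and lowered all 36 tested G2/M genes. The median change of all 13012 genes was 0.22, and it was 0.02 with median-of-ratios scaling and −0.03 with quantile normalization, so gene and list values for this comparison are given relative to that 0.22. GDF15, a stress-induced cytokine, rose from 45.4 to 1032 TPM (4.26 ± 0.07). CDKN1A rose from 49.5 to 883 TPM (3.91 ± 0.07), the transcriptional repressor HES1 from 15.3 to 303 TPM, the kinase PLK2 from 7.09 to 121 TPM (3.73 ± 0.19) and the AP-1 subunit FOSL1 from 1.82 to 36.6 TPM (3.50 ± 0.15). DUX4, a gene of repeated copies whose level is therefore uncertain, was at 1.97 TPM with DMSO and 170 TPM with luteolin. The immunoproteasome subunit PSMB9 fell from 30.6 to 4.61 TPM (−2.71 ± 0.17), the interferon-induced IFI35 fell (−2.34 ± 0.12), and the metallothionein MT1X fell from 159 to 35.6 TPM (−2.35 ± 0.08). PALM3 (−2.41 ± 0.09), LIMD2 (−2.38 ± 0.12) and the endocytic GTPase DNM3 (−2.33 ± 0.08) fell as well. In all, 5938 genes were higher and 2585 lower (69.7% higher), 1294 and 202 of them by at least 2-fold. With median-of-ratios scaling 4241 were higher and 4213 lower (50.2% higher), and with quantile normalization 3697 and 4256 (46.5% higher). The share of TPM on retained-intron transcripts was 3.39% ± 0.114 with DMSO and 5.23% ± 0.158 with luteolin (SD, n = 3), and mitochondrial mRNAs took 7.10% ± 1.03 and 10.5% ± 1.40.

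The p53 targets stood apart in A2780 with luteolin: 30 of 31 were higher and 0 lower under either adjustment and with median-of-ratios scaling (median 1.74, adjusted p = 1.75e-15, and adjusted p = 0.0515 with an estimated correlation). All 36 tested G2/M genes were lower under either adjustment and with that scaling (median −1.09, adjusted p = 1.42e-20, and adjusted p = 0.15 with an estimated correlation), with the mitotic kinase PLK1 falling from 141 to 44.8 TPM (−1.87 ± 0.11) and cyclin B2, CCNB2, at −1.49 ± 0.10. Of 40 G1/S genes 32 were lower and 1 higher under either adjustment, and 38 and 0 with that scaling (median −0.84, adjusted p = 1.77e-15, and adjusted p = 0.154 with an estimated correlation). The thymidine kinase TK1 (−1.62 ± 0.08) and the methylation cofactor UHRF1 (−1.47 ± 0.06) were among them. All 19 immediate early genes were higher under either adjustment, and 17 with that scaling (median 0.94, adjusted p = 1.3e-06, and adjusted p = 0.0515 with an estimated correlation), FOS at 2.34 ± 0.16.

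Integrated stress response, ER chaperone and NRF2 lists rose in the same comparison, and cholesterol, heat shock and oxidative phosphorylation lists fell. Of 27 integrated stress response genes 19 were higher and 3 lower under either adjustment, and 17 and 8 with median-of-ratios scaling (median 0.36, adjusted p = 0.00401, and adjusted p = 0.252 with an estimated correlation). ATF3 (2.71 ± 0.14) and DDIT3 (2.27 ± 0.09), transcription factors of that response, were higher. Of 20 ER chaperone genes 16 were higher and 1 lower under either adjustment, and 12 and 3 with that scaling (median 0.40, adjusted p = 0.00258, and adjusted p = 0.28 with an estimated correlation), with HERPUD1 at 1.79 ± 0.07. NRF2 targets had 16 of 24 higher and 3 lower, or 17 and 3 adjusted over the list alone, and 13 and 6 with that scaling (median 0.26, adjusted p = 0.0124, and adjusted p = 0.272 with an estimated correlation), with HMOX1 at 2.81 ± 0.09 and the quinone reductase NQO1 at 1.03 ± 0.04. Cholesterol genes fell, with 19 of 24 lower and 2 higher, or 19 and 3 adjusted over the list alone, and 20 and 1 with that scaling (median −0.79, adjusted p = 2.36e-09, and adjusted p = 0.148 with an estimated correlation), among them FDPS (−1.61 ± 0.04, 430 to 163 TPM) and EBP (−1.58 ± 0.05). Heat shock genes had 15 of 17 lower and 2 higher under either adjustment and with that scaling (median −0.84, adjusted p = 1.64e-08, and adjusted p = 0.15 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 22 of 31 lower and 4 higher under either adjustment, and 27 and 0 with that scaling (median −0.52, adjusted p = 3.35e-09, and adjusted p = 0.148 with an estimated correlation), COX5B at −0.86 ± 0.04. Targets of the aryl hydrocarbon receptor (4 of 5 higher, 3 with that scaling) and NF-kB genes (7 of 12 higher, also with that scaling) passed too. So did autophagy and lysosome genes (17 of 25 higher, but 13 higher and 4 lower with that scaling). Interferon-stimulated genes passed with more falls than rises (11 of 28 lower and 6 higher, 14 and 3 with that scaling). Matrix genes passed until the libraries were rescaled by median of ratios (16 of 26 higher, but 13 higher and 5 lower with that scaling). Of 6 fibroblast markers 3 were lower and 0 higher. Of the 22 lists 15 passed, and 0 did with an estimated correlation.

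Luteolin in ES2 raised the integrated stress response genes and lowered most genes of the G2/M, heat shock, and hypoxia and glycolysis lists. CHAC1, a glutathione-degrading enzyme of that response, went from 0.720 to 23.5 TPM and the stress-induced chromatin protein NUPR1 from 1.27 to 28.9 TPM, from controls near 1 TPM. The asparagine synthetase ASNS rose from 19.1 to 175 TPM (3.13 ± 0.08), DDIT4, an inhibitor of mTOR signalling, from 10.3 to 113 TPM (3.32 ± 0.14) and SESN2 from 4.79 to 39.1 TPM (2.79 ± 0.08). The fall of the collagen chain COL1A1, which is also a fibroblast marker, was from 115 to 13.0 TPM (−3.07 ± 0.13), and that of the cadherin CDH5, also an endothelial marker, from 37.8 to 8.86 TPM (−1.98 ± 0.05). ANKRD1, a transcriptional cofactor of striated muscle, fell from 105 to 15.0 TPM (−2.72 ± 0.06), and CAVIN3 of caveolae fell (−2.06 ± 0.07). In all, 2826 genes were higher and 3228 lower of 12507, 306 and 147 of them by at least 2-fold. Mitochondrial mRNAs took 4.57% ± 0.564 of the TPM with DMSO and 7.78% ± 0.791 with luteolin (SD, n = 3), and without them 3349 genes were higher and 2763 lower, a comparison added after the data had been seen.

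All 26 tested integrated stress response genes rose in ES2 with luteolin, under either adjustment (median 1.51, adjusted p = 4.59e-24, and adjusted p = 0.0103 with an estimated correlation). G2/M genes fell, with 35 of 36 lower, or 36 adjusted over the list alone (median −0.59, adjusted p = 1.93e-18, and adjusted p = 0.0103 with an estimated correlation), KIF20A at −1.34 ± 0.06 and PLK1 at −1.17 ± 0.05. Of 17 heat shock genes 16 were lower, or 17 adjusted over the list alone (median −0.54, adjusted p = 4.42e-12, and adjusted p = 0.0103 with an estimated correlation), HSPB1 at −1.28 ± 0.04. Hypoxia and glycolysis genes had 23 of 28 lower and 3 higher under either adjustment (median −0.53, adjusted p = 2.33e-08, and adjusted p = 0.0134 with an estimated correlation). The lactate dehydrogenase LDHA fell from 1709 to 733 TPM (−1.22 ± 0.04), while the growth factor VEGFA rose (1.23 ± 0.05).

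Further lists passed in ES2 with luteolin at the preset correlation alone. Immediate early genes had 16 of 18 higher under either adjustment (median 1.06, adjusted p = 5.55e-09, and adjusted p = 0.227 with an estimated correlation). NF-kB and inflammatory genes had 18 of 22 higher and 1 lower under either adjustment (median 0.94, adjusted p = 6.53e-07, and adjusted p = 0.196 with an estimated correlation), with the cyclooxygenase PTGS2 at 1.61 ± 0.20. Cholesterol genes had 18 of 24 lower under either adjustment (median −0.41, adjusted p = 3.37e-07, and adjusted p = 0.0598 with an estimated correlation). Of 40 G1/S genes 21 were lower and 2 higher under either adjustment (median −0.19, adjusted p = 0.000928, and adjusted p = 0.419 with an estimated correlation). The p53 targets had 8 of 29 higher and 3 lower, or 8 and 2 adjusted over the list alone (median 0.08, adjusted p = 0.0346, and adjusted p = 0.411 with an estimated correlation). Ribosome biogenesis genes had 15 of 30 lower and 4 higher, or 17 and 4 adjusted over the list alone (median −0.19, adjusted p = 0.0174, and adjusted p = 0.411 with an estimated correlation), the nucleolar protein NCL at −0.51 ± 0.05, while MYC of that list was higher (0.82 ± 0.07). Nuclear genes of oxidative phosphorylation had 12 of 31 lower and 5 higher, or 14 and 5 adjusted over the list alone (median −0.10, adjusted p = 0.0346, and adjusted p = 0.227 with an estimated correlation). Nuclear envelope genes and VRK1 substrates had 7 of 17 lower and 1 higher under either adjustment (median −0.13, adjusted p = 0.0355, and adjusted p = 0.227 with an estimated correlation).

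Across the lines, luteolin moved more genes the same way than independent lists would give. Of 11304 genes, 1757 were higher in both (1188 expected) and 1188 lower in both (591 expected). Of the genes called in both, 76.2% moved the same way (48.9% expected), with r = 0.42 across genes. GDF15, ATF3, FOS, DDIT3 and the NF-kB regulator NFKBIZ rose in both lines. PLK1, the histone chaperone ANP32E, the cytokinesis protein ANLN and the lactate transporter SLC16A3 fell in both. The actin-bundling LCP1 fell in A2780 and rose in ES2, and NMNAT2, an enzyme of NAD synthesis, did the reverse.

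The response to luteolin differed between the lines for the p53 targets and the integrated stress response. The effect in ES2 minus that in A2780 was positive for 2104 genes and negative for 5125 of 14328 (29.1% positive), and for 3472 and 3641 with median-of-ratios scaling (48.8%) and 3621 and 3266 with quantile normalization (52.6%). Its median over all genes was −0.20 and moved to −0.03 with median-of-ratios scaling, so the values that follow are relative to −0.20. For the p53 targets 30 of 32 were lower in ES2 and 1 higher under either adjustment and with that scaling (median −1.29, adjusted p = 2.24e-13, and adjusted p = 0.0147 with an estimated correlation), with PLK2 at −3.80 ± 0.23. For the integrated stress response 22 of 27 were higher and 2 lower, or 23 and 2 adjusted over the list alone and with that scaling (median 1.22, adjusted p = 4.14e-20, and adjusted p = 0.00933 with an estimated correlation). ASNS was at 3.41 ± 0.09: in A2780 it was at 239.5 TPM with DMSO and 225.3 TPM with luteolin. G1/S genes (25 of 40 higher and 2 lower, or 26 and 2 adjusted over the list alone, 33 and 1 with that scaling, median 0.61, adjusted p = 5.67e-11, and adjusted p = 0.213 with an estimated correlation) and G2/M genes (21 of 36 higher and 1 lower, or 22 and 1, and 27 and 1 with that scaling, median 0.53, adjusted p = 2.78e-08, and adjusted p = 0.26 with an estimated correlation) were less negative in ES2. ER chaperone genes were more positive in A2780 (18 of 20 lower in the difference and 1 higher under either adjustment, 15 and 1 with that scaling, median −0.41, adjusted p = 2.95e-05, and adjusted p = 0.213 with an estimated correlation). PSMB9 (3.31 ± 0.22) was among the most positive single genes, and HES1 (−3.79 ± 0.42) and CCN2 (−3.56 ± 0.15) among the most negative.

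**Figure D3:**
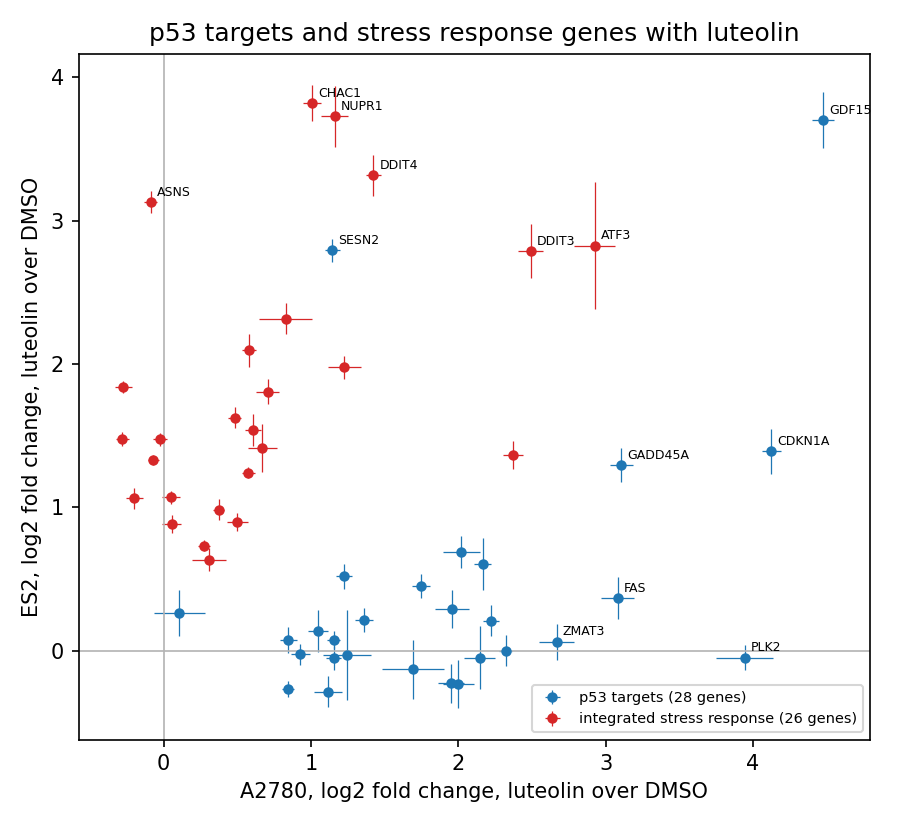
The log2 fold change with luteolin in A2780 (horizontal axis) against ES2 (vertical axis) for 28 p53 targets and 26 integrated stress response genes, with standard errors of the fit as bars (3 luteolin and 3 DMSO libraries per line). The p53 targets spread along the A2780 axis (list medians 1.96 in A2780 and 0.08 in ES2). The integrated stress response genes are all above 0 on the ES2 axis (list median 1.51). Values and list medians are as fitted, without subtracting the median of all genes, and list medians cover all members tested in the line.

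Within each line, siVRK1 and luteolin shared some changes. In A2780, 992 genes were higher with both (821 expected) and 1124 lower with both (699 expected), 57.5% of the genes called in both moved the same way (43.6% expected), and r was 0.20 across genes. CCN2 and ACTA2 rose with both, as did the matrix protein THBS1, and the nucleosome-binding HMGN5 and IFI35 fell with both. The ubiquitin-like interferon-stimulated gene ISG15 rose with siVRK1 (1.32 ± 0.06) and fell with luteolin (−0.94 ± 0.06 as fitted, without subtracting the median), and the transcription factor KLF2 fell with siVRK1 (−1.34 ± 0.12) and rose with luteolin. In ES2, 865 genes were higher with both (757 expected) and 1236 lower with both (905 expected), 57.1% moved the same way (50.1% expected), and r was 0.07. The phosphatase DUSP10 and CDKN1A rose with both, and ANKRD1, TGFBI and NMNAT2 fell with both. KIF20A rose with siVRK1 (1.38 ± 0.06) and fell with luteolin (−1.34 ± 0.06), and ANGPTL4, an inhibitor of lipoprotein lipase, fell with siVRK1 (−2.44 ± 0.18) and rose with luteolin (1.90 ± 0.18). The treatments shared no control libraries. Within a line they did share the estimate of the spread of each gene. Genes of low spread can therefore be called with both more often than expected from independent lists.

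The difference between the treatments was tested in each line, each effect being taken against its own control. The controls of a line differed too, CDKN1A in A2780 being higher with siCtrl than with DMSO. A difference of effects can therefore rest partly on the controls. In A2780 the luteolin effect was higher than the siVRK1 effect for 5631 of 13012 genes and lower for 1861 (75.2% higher), against 3538 and 3696 with median-of-ratios scaling (48.9%) and 3118 and 3511 with quantile normalization (47.0%). The median difference of all genes was 0.30 and moved to 0.02 with median-of-ratios scaling. Relative to 0.30, HES1 (4.35 ± 0.12) and KLF2 (3.66 ± 0.17) were among the most positive and TNNC1, a muscle troponin (−2.65 ± 0.14), among the most negative. The p53 targets were higher with luteolin in 30 of 31 cases under either adjustment and with that scaling (median 1.49, adjusted p = 4.3e-14, and adjusted p = 0.0632 with an estimated correlation). In ES2, 3233 of 12507 were higher and 3252 lower. All 26 integrated stress response genes were higher with luteolin under either adjustment (median 1.56, adjusted p = 3.47e-17, and adjusted p = 0.036 with an estimated correlation), G2/M genes were lower (30 of 36 and 2 higher, or 31 and 2 adjusted over the list alone, median −0.63, adjusted p = 1.26e-11, and adjusted p = 0.036 with an estimated correlation), and VRK1 itself was at 3.83 ± 0.15.

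The control libraries of the lines, given a control siRNA or DMSO, differed widely. Taking siCtrl and DMSO libraries together, 4909 genes were higher and 7081 lower in ES2 than in A2780 of 14328. The median difference was −0.17, and −0.03 with median-of-ratios scaling, and values are relative to −0.17. The calcium-binding S100A6 was at 1752 TPM in ES2 siCtrl and 0.539 TPM in A2780 siCtrl (10.30 ± 0.11), and the collagenase MMP1 at 7004 and 11.3 TPM (9.88 ± 0.06). MEST was at 2206 TPM in A2780 siCtrl and 1.30 TPM in ES2 siCtrl (−9.85 ± 0.21). The growth factor HGF (771 TPM in A2780 siCtrl) and the myosin light chain MYL9 (435 TPM) were listed at 0 in the ES2 controls, and the lipase inhibitor G0S2 (1816 TPM in ES2 siCtrl) at 0 in the A2780 controls. NF-kB genes had 18 of 22 higher in ES2 and 3 lower under either adjustment and with that scaling (median 1.67, adjusted p = 7.34e-05, and adjusted p = 0.218 with an estimated correlation). The p53 targets had 26 of 32 lower and 3 higher under either adjustment, and 25 and 4 with that scaling (median −1.02, adjusted p = 0.000655, and adjusted p = 0.218 with an estimated correlation), and the integrated stress response had 24 of 27 lower and 2 higher, and 23 and 3 with that scaling (median −1.24, adjusted p = 5.34e-05, and adjusted p = 0.218 with an estimated correlation).

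Marker lists of leukocytes, endothelium, erythroid cells and melanocytes had medians below 1 TPM in each group, with up to 3 genes at 1 TPM or more. Of 9 fibroblast markers 5 or 6 reached a mean of 1 TPM in each A2780 group (medians of 2.01 to 3.15 TPM) and 3 in each ES2 group. Group means of the leukocyte marker CD68 ran from 36.7 to 75.4 TPM in ES2 and from 2.18 to 3.50 TPM in A2780. The endothelial EGFL7 ran from 21.3 to 35.5 TPM in A2780 and CDH5 from 8.86 to 37.8 TPM in ES2. The fibroblast COL3A1 ran from 47.2 to 68.6 TPM in A2780 and COL1A1 from 13.0 to 115 TPM in ES2. The highest erythroid marker in A2780 was HBA1, at 1.69 to 4.10 TPM, and the highest mean of any in ES2 was 0.239 TPM. The melanocyte factor MITF reached 8.78 TPM in ES2.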

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

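The depth-of-knockdown test, the exchange of libraries between pairs, which replaced a planned exchange within pairs because that one removes the response itself, the use of the spread between leave-one-out values in the test of few reads, and the test of the 10 most abundant genes, which replaced one that could not come out otherwise, were chosen only after the result was seen. The tests of scaling, of the GATAATA word in the G1/S list, and of olfactory receptor genes were written down first.

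The response to siVRK1 differed between the lines, more positive in ES2 for 2962 genes and more negative for 1897, a majority that turned with median-of-ratios scaling (2255 and 2762). With the level of each line taken out, treated libraries were exchanged with treated and controls with controls between the lines. Of 100 such groupings 1, the real one, gave as many calls as 4859, while the highest other gave 1506. Chance in the grouping of these libraries was thus excluded. A chance difference between single cultures was not, because the libraries of a group may be technical repeats. On the positive side stood G1/S (median difference 0.92, adjusted p = 0.0668 with an estimated correlation) and G2/M (0.63, adjusted p = 0.207 with it), which passed at the preset correlation alone. On the negative side targets of the aryl hydrocarbon receptor (−0.51, adjusted p = 0.0175) and matrix genes (−0.48, adjusted p = 0.0237) passed with an estimated correlation too. Single genes differed for unlike reasons. CHRDL1 (3.47 ± 0.19), IL11 (2.94 ± 0.34) and MMP3 (2.79 ± 0.15) rose in ES2, while MMP3 was at 42.6 TPM with siCtrl and 29.1 TPM with siVRK1 in A2780. COL6A3 (−3.61 ± 0.11) fell in ES2 from a level like that of A2780, 64.6 against 71.4 TPM with siCtrl. With DMSO in ES2 COL6A3 was at 15.2 TPM and ESM1 at 308 TPM, so both varied between the control groups of that line. CCN2 (−3.34 ± 0.15) rose in A2780 and fell in ES2, and ACTG2 (−3.26 ± 0.22) rose in A2780. ESM1 (2.86 ± 0.08) and KRT79 (−3.03 ± 0.15) were listed at 0 in A2780, and MYL7 (−3.16 ± 0.30) at 0 in ES2, so their differences rest on 1 line. The value for the histone pseudogene H3P6 (3.20 ± 0.47) is uncertain because near-identical copies share its reads.

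That G1/S genes were lower in A2780 and higher in ES2 with siVRK1 was weighed against 3 explanations. If scaling between libraries had made it, median-of-ratios scaling would have removed the median difference, which was 0.82 with it, so scaling was ruled out as the whole cause. If an off-target siRNA seed match in 3′ UTRs had made it, leaving out members with GATAATA would have too, and the median difference was 0.92 without them. Only 2 of 40 members held the word, too few for their removal to move the median much, so this test could not decide. The count shows only that most members held no such site in the 3′ UTR searched, and an effect passed on through other genes was not tested. The difference between the lines in depth of knockdown, −1.40 ± 0.16 on the log2 scale for VRK1, may have contributed, and with 1 VRK1 level per line this stays undecided.

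The response to luteolin differed as well, positive for 2104 genes and negative for 5125 as fitted (3472 and 3641 with median-of-ratios scaling), where the median of all genes was −0.20 and is not subtracted from the values in this paragraph. Of 100 groupings exchanged between the lines in the same way, 1, the real one, gave as many calls as 7229, and the highest other gave 3915. Chance in the grouping of these libraries was thus excluded, but not a chance difference between single cultures. The p53 target list had a median of −1.48 and the integrated stress response 1.02, and both passed with an estimated correlation. G1/S (0.42, adjusted p = 0.213 with it) and G2/M (0.33, adjusted p = 0.26 with it) passed at the preset correlation alone. ASNS (3.22 ± 0.09) and CHAC1 (2.82 ± 0.13) rose in ES2 from controls of 19.1 and 0.720 TPM, against controls of 239.5 and 62.9 TPM in A2780. PSMB9 (3.12 ± 0.22) and LCP1 (2.71 ± 0.18) fell in A2780 and were higher with luteolin in ES2, and PAPPA2 (3.15 ± 0.25) rose in ES2. PLK2 (−3.99 ± 0.23), HES1 (−3.98 ± 0.42), SULF2 (−4.33 ± 0.18) and CCN2 (−3.76 ± 0.15) rose in A2780, and PLK2 was at 134 TPM with DMSO and 131 TPM with luteolin in ES2. The value for DUX4 (−5.52 ± 0.61) is uncertain because of its repeated copies.

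More rises than falls with luteolin in A2780 came with a higher share of TPM on retained-intron transcripts, 5.23% against 3.39% with DMSO, where the siRNA groups stood between at 4.49% (siCtrl) and 4.38% (siVRK1), and no comparison in the design addressed it. A first explanation was genomic DNA or unspliced RNA in the libraries. Genomic DNA would raise silent genes, while unspliced RNA of expressed genes would not, so the test bears on genomic DNA alone. The summed TPM of 409 olfactory receptor genes was 2.26 times that with DMSO, with ranges apart (28.4 to 31.7 against 11.7 to 14.2). The sum thus met its bound, although siCtrl also stood above DMSO there (from 20.2). Any cause that lifts genes of low level would raise this sum too, so it cannot single out genomic DNA. Its size, weighed after the result was seen, argues against genomic DNA for genes of 10 to 50 TPM. The sum over all 409 genes was at most 31.7 TPM, while the median log2 fold change of genes of 10 to 50 TPM was 0.22. In ES2 the sum was likewise higher with siVRK1 (28.0 to 32.9) than with siCtrl (22.4 to 24.8), with ranges apart, while only 48.9% of those calls were higher. With siVRK1 in A2780 the ranges overlapped, and with luteolin in ES2 the sum was lower (29.7 to 32.0 against 33.9 to 36.0). A higher sum thus need not come with an excess of rises. Had few reads in the DMSO libraries left low genes at 0, the excess would have vanished among genes of at least 10 TPM. There 61.3% of calls were higher, past the bound of 60 written beforehand. Yet leaving out 1 library gave 58.8% to 64.2%, and with that spread the question was left undecided. Transcripts above 0 numbered 79102 to 84882 with DMSO, 93770 to 95746 with luteolin and 88481 to 92374 with siCtrl. Fewer reads and fewer expressed transcripts with DMSO would both give such counts, so they cannot decide it. The excess fell with level and turned round, from 90.2% higher below 2 TPM and 85.5% at 2 to 10 TPM to 73.6% at 10 to 50 TPM and 41.1% (892 higher and 1279 lower) from 50 TPM. A smaller share of a few abundant genes was argued against, because the 10 most abundant took more with luteolin (mean 12.2% of the TPM of genes with a symbol, 11.5% to 13.4%, against 9.41% to 10.7% with DMSO) and the top 100 overlapped (37.1% to 38.9% against 35.3% to 38.1%), while a fall over the top 1000 (67.5% to 68.4% against 69.6% to 71.8%) goes with the change by level.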

How the results depend on the processing

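The block with the unnumbered libraries in the other order and the removals of mitochondrial mRNAs and of genes with the GATAATA word were chosen only after results had been seen. Scaling changed the split of calls. For luteolin in A2780 median-of-ratios scaling gave 4213 lower genes instead of 2585, and quantile normalization 3697 higher and 4256 lower. For the difference of the luteolin effects between the lines they gave 3472 higher, and 3621 higher and 3266 lower, against 2104 and 5125. For the difference between the treatments in A2780 they gave 3538 higher and 3696 lower, and 3118 and 3511, against 5631 and 1861. For the difference of the siVRK1 effects between the lines they gave 2255 higher and 2762 lower, and 2511 and 2347, against 2962 and 1897. TPM does not show which scaling is right, because total RNA per cell and depth are unknown. Of 3 technical explanations weighed for the imbalance with luteolin in A2780, a smaller share of abundant genes was argued against and few reads stayed open. Genomic DNA met its test, but the signal was too small to account for the rises at 10 to 50 TPM. Unspliced RNA was not tested. The cause of the shift between scalings in the differences of effects was not tested either. SC5D in A2780 with luteolin changed sign, to −0.0303, with quantile normalization, where it was not called (adjusted p = 0.776). VRK1 in ES2 with luteolin, not called to begin with, ranged from −0.0518 without ES2 luteolin library 3 to 0.114 without ES2 luteolin library 2, while with siVRK1 it ranged from −2.52 to −2.29 in A2780 and from −3.88 to −3.67 in ES2. The number of lists past the threshold depended on the correlation between genes. With an estimated correlation it went from 7 to 0 for A2780 siVRK1, 15 to 0 for A2780 luteolin, 6 to 0 for ES2 siVRK1 and 12 to 4 for ES2 luteolin. It went from 8 to 2 for the siVRK1 difference between lines, 12 to 2 for the luteolin difference, 13 to 0 and 11 to 3 for the differences between treatments in A2780 and ES2, and 10 to 0 for the controls. With fry it rose to 18 for A2780 siVRK1, 17 for ES2 siVRK1, 20 for the luteolin difference, 19 for the treatments in ES2 and 22 for the controls. With the replicate block the counts were 1690 higher and 3359 lower for A2780 siVRK1, 5820 and 2533 for A2780 luteolin, 3309 and 3477 for ES2 siVRK1, and 2787 and 3182 for ES2 luteolin. Same-numbered libraries correlated at −0.05 to 0.04 after removal of group means, so the numbers do not pair them. Pseudocounts, filters and other sets of libraries moved no count of calls by as much as 1.5 times.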

Other observations

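The test in ES2, the test of other words of the same bases, the exchange of libraries between treatments and the correlation without word genes were chosen only after the result was seen, and the search over all 7-base words was itself unplanned and covered the 4 treatment comparisons. The tests of the VRK1 transcript and of the reverse complement were written down first.

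Nuclear envelope genes and known VRK1 substrates differed between the lines in their response to siVRK1. In A2780 8 of 17 were lower and 1 higher, or 8 and 2 adjusted over the list alone and 8 and 5 with median-of-ratios scaling (median −0.34, adjusted p = 0.264), and in ES2 9 were higher and 4 lower (median 0.15, adjusted p = 0.136), so neither passed alone. The difference between the lines passed, with 10 of 17 higher in ES2 and 0 lower, or 9 and 0 with that scaling (median 0.36, adjusted p = 0.00218, and adjusted p = 0.215 with an estimated correlation). TMPO, a lamin-binding protein, was lower in A2780 (−0.74 ± 0.11), and lamin B2, LMNB2, was higher in ES2 (0.89 ± 0.03).

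The falls with siVRK1 that both lines shared were enriched for GATAATA in the 3′ UTR. It was picked because it ranked 1 of 15979 words in A2780. There 720 genes with it differed in median by −0.28 ± 0.02 (bootstrap SE) from the others. In ES2 it ranked 1 of 15947 words (712 genes, −0.39 ± 0.02), while with luteolin the differences were 0.16 and −0.02. Its adjusted z was −18.2 and −18.8, against −5.21 and −4.29 for the next unrelated word. In A2780 the median was −0.08 with 0 sites, −0.30 with 1 site not followed by A, −0.45 with 1 followed by A and −0.57 with at least 2. In ES2 the values were −0.003, −0.33, −0.53 and −0.36. These medians were not adjusted for 3′ UTR length or base content. With luteolin in A2780 they varied as well, from 0.16 with 0 sites to 0.40 with at least 2. Of 1635 searched genes lower in both lines 349 (21.3%) held the word, against 5.55% of other genes, so most shared falls did not hold it.

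For the siVRK1 falls shared by both lines, an off-target siRNA seed match in 3′ UTRs is a possible explanation: the word found in A2780 ranked 1 in ES2, and the site in the VRK1 mRNA occurs 1 time, as it would if the siRNA carried that seed, where 4.67% of transcripts of like length hold the word. The strand test was undecided, because the reverse complement gave −0.0671 in A2780 and −0.05 in ES2, between the bounds set beforehand. These differences of medians were not adjusted for length and GC content. With that adjustment its z was −2.49 in A2780 and −2.04 in ES2, against −18.2 and −18.8 for the word. The association was thus far weaker for the reverse complement. Base content and length of 3′ UTRs were ruled out as the whole cause, since in ES2, after adjustment for length and GC content, the lowest z of 91 other words of the same bases was −3.37 against −18.8 for the word. Lower VRK1 itself may account for the rest, but that too is undecided. The fold changes of the lines correlated at 0.40 without genes holding the word. That value cannot tell lower VRK1 from off-target effects, because the lines could also share off-target effects in genes without the word. The sequence of the siRNA is not given in the sources used here, and a second siRNA or a rescue of VRK1 would separate these.

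The grouping of libraries was exchanged to see how many calls arise without the real groups. For the 3 with 3 comparisons there are 10 splits, too few for a share under 0.05. The real grouping, the 1 split with as many calls in each, gave 5318 calls for A2780 siVRK1 (highest other 1), 8523 for A2780 luteolin (0), 6856 for ES2 siVRK1 (0) and 6054 for ES2 luteolin (2). For the difference between treatments, libraries were exchanged between the treatments and between their controls with the level of each pair taken out. In A2780 1 of 100 groupings, the real one, gave as many as 7492 calls (highest other 1706), and in ES2 1 of 100 gave as many as 6485 (highest other 1). Chance in the grouping of these libraries was thus excluded in both. For the control lines 1 of 100 gave as many as 11990 (highest other 9845), and such chance was excluded there too. None of these exchanges can exclude a chance difference between single cultures, because the libraries of a group may be technical repeats.

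Another pattern with siVRK1 concerns the rises. The word GCAGTAC was picked because it ranked 1 among words of rises in A2780, and it ranked 1 in ES2 as well. The differences of medians were 0.15 in A2780 and 0.29 in ES2, and the word occurs 0 times in the VRK1 transcript. A seed in the control siRNA, whose targets would be lower in siCtrl, was not tested.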
